A study of Capsicum chinense and Capsicum frutescens with 8 samples.

How the data were processed

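Small RNAs were measured in stem, flower, fruit and leaf of 2 cultivated peppers, Bhut jolokia (Capsicum chinense), a very pungent chilli, and an accession of C. frutescens. Per the labels' protocols, RNA of 3 biological replicates was pooled before each of the 8 libraries was made, so every species and tissue is represented by 1 library. The fruit libraries pool stages from 5 to 60 days after flower opening. Per the labels' protocols, RNA was extracted with a NucleoSpin kit, and TruSeq small RNA libraries were read on an Illumina Genome Analyser II.

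Per the file headers, the authors deposited raw read counts for each miRNA entry of each library, in 16 sheets, 8 for conserved entries and 8 for predicted miRNAs. The counts are whole numbers that go down to 1 read, and their totals differ between libraries. The adapter trimming, the aligner, the miRNA database release, the allowed mismatches and the tool that predicted miRNAs are not given in the sources used here. Conserved entries carry names of 57 species prefixes, none of an animal, so the list fixed for animal entries had no member. Each entry has 1 printed sequence, and 94.2% of the 1247 conserved entries listed in at least 2 libraries had more than 1 sequence over the libraries. The printed sequences of conserved entries run from 16 to 36 nt and were therefore not read as mature forms. Entries with a printed sequence over 24 nt held most reads, from 84.9% in C. frutescens leaf to 98.9% in C. chinense stem. Shares of a family are thus shares of the reads listed under its names, and not of reads known to have mature length. In the sheets of conserved entries for C. chinense stem and C. chinense leaf, 1 line each was empty in the copies used here, between entries of 1 read. An entry that a sheet does not list entered as 0 reads. The sheets list miRNA reads only, so the number of reads sequenced per library is unknown and shares refer to the listed conserved reads.

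Reads of entries with the same miR number were summed to families with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The species and tissue comparisons used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on these sums, with TMM scaling, a filter of at least 10 reads in at least 2 libraries, and the additive model tissue plus species. The model leaves 3 residual degrees of freedom, and its error is the variation of the species difference between tissues. The test adds 7.10 prior degrees of freedom drawn from all families, so a p-value leans partly on the spread of other families. Each tissue was compared with the mean of the other 3. Standard errors of log2 fold changes were computed from the F statistics. P-values were adjusted by the Benjamini-Hochberg method within each contrast, with a threshold of 0.05. Lists of families fixed by textbook function were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The fry test, also run, compares a list with no change and not with the other families. Within a tissue, where 1 library stands against 1, ratios of shares are given with 95% counting intervals, and families with at least 50 reads in both libraries together were counted as apart at 4-fold or more. Shares have exact Clopper-Pearson 95% intervals, and a family without reads in a library was given a floor of 3 reads. Reads carry no molecular identifiers, so intervals and floors cover counting error only. Spearman correlations, Fisher's exact tests and exact permutation tests were computed with scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

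The families named were chosen by a rule. For composition these are the 10 with the highest mean share. For the species comparison they are those past the threshold that point one way in all 4 tissues or, if fewer than 5 pass, the 10 largest changes that point one way. For each tissue they are the calls or, without calls, the 3 largest per direction, in either case only among families with the same direction in both species. Within a tissue they are the 3 largest ratios per direction, and for predicted miRNAs the 5 sequences with most reads and those listed in 4 or more libraries. From each list 2 to 4 members with the highest mean share are named. The tests, this rule, the lists and most alternatives were fixed before the data were examined. A few alternatives were added later and are named as such in the closing part.

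Alternatives were DESeq2 size factors in the same fit, total listed reads without TMM, the tests of DESeq2 1.42.0 and of limma-voom, other filters, distinct sequences or entry names as the unit, models without the block, each library left out in turn, and the removal of miR166, of rRNA and tRNA fragment entries, or of the leaf or fruit pair. The fit was tested on simulated counts drawn for the 71 tested families, of which 20 were changed, in 20 simulations. For the species contrast it recovered 1.25% of the families changed 4-fold, 48.8% of those changed 16-fold and 94.2% of those changed 64-fold. For the fruit contrast these shares were 3%, 43.8% and 82%. At most 1.37% of the unchanged families were called.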

Results

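Conserved and predicted miRNAs were counted in 8 small RNA libraries, 1 each for stem, flower, fruit and leaf of C. chinense and C. frutescens. The series set out to catalogue the miRNAs of both species, from 1 genotype each with contrasting fruit. The listed conserved reads per library numbered 1412110, 1079538, 613569 and 811863 in C. chinense stem, flower, fruit and leaf. In the same tissues of C. frutescens they numbered 1132791, 412734, 937585 and 246508. With 1 library of pooled RNA per group there is no replicate of a group. P-values weigh a difference against its variation over the 4 tissues or both species, with an error partly shared over families. They speak of these genotypes and libraries.

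Over all libraries 1336 conserved families were listed, of which 102 appeared in all 8 libraries and 548 (41.0%) in 1 library. C. frutescens fruit listed 1008 families, the highest number, and C. frutescens leaf listed 258, the lowest. C. chinense stem, flower, fruit and leaf listed 415, 319, 315 and 529 families, and C. frutescens stem and flower 530 and 302. After every library was thinned to 246508 reads, C. frutescens fruit listed 457 families on average and the other libraries between 154 and 258. In C. chinense 809 families were listed in any tissue, in C. frutescens 1176, and in both species 649. C. frutescens fruit alone listed 331 families, none with more than 10 reads. The 71 families that passed the filter held at least 99.5% of the reads of every library.

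miR166, which targets HD-ZIP III transcription factors of leaf polarity and meristems, took most of the reads, with a mean share of 73.0% ± 17.8 (SD, n = 8 libraries). Its share was 84.3% ± 13.9 (SD, n = 4) over the C. chinense tissues and 61.6% ± 14.3 (SD, n = 4) over those of C. frutescens. The lowest share was 42.5% in C. frutescens flower (95% interval 42.4 to 42.7) and the highest 93.9% in C. chinense flower (93.8 to 93.9). miR482, which targets NBS-LRR resistance genes, followed with 10.7% ± 5.35 (SD, n = 8), from 4.13% in C. chinense flower to 20.7% in C. frutescens flower. miR6300, an entry often traced to tRNA fragments, took 5.84% ± 4.82, and miR3711 took 4.91% ± 8.40.

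The share of miR3711 was 24.7% in C. frutescens flower and 6.50% in C. chinense leaf, against 4 reads, 1 read and 1 read in C. chinense stem, flower and fruit. miR894, an entry often traced to rRNA or tRNA fragments, had a mean share of 0.982% ± 1.66. It was also listed with 4 reads, 1 read and 1 read in those 3 libraries. The origin of such fragment entries was not checked in these data. In C. frutescens fruit miR396, which targets growth-regulating factors, reached 4.76%, miR162, which targets the Dicer-like enzyme of miRNA maturation, 2.78%, and miR159, a regulator of GAMYB genes, 2.47%. Mean shares over the 8 libraries were 0.760% ± 1.62 for miR396, 0.606% ± 0.912 for miR162 and 0.534% for miR159, which ranged from 0.00982% to 2.47%. miR168, which targets AGO1, and miR8175 had 0.409% ± 0.368 and 0.327% ± 0.337.

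**Figure D1:**
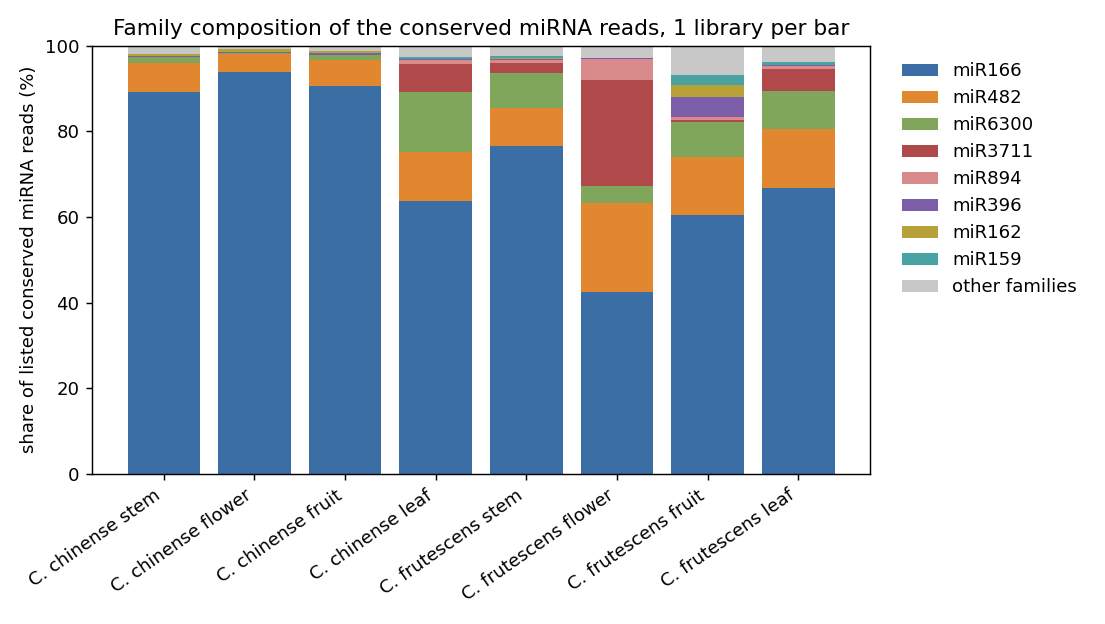
Share of the listed conserved miRNA reads (%, vertical axis) taken by the 8 families with the highest mean share and by all others, 1 stacked bar per library. miR166 ranges from 42.5% in C. frutescens flower to 93.9% in C. chinense flower, and miR3711 takes 24.7% in C. frutescens flower.

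Between the species, miR2599 was higher in C. chinense in all 4 tissues, with 51, 63, 15 and 23 reads in stem, flower, fruit and leaf against 1, 0, 1 and 1 in C. frutescens. Its log2 fold change (C. frutescens over C. chinense) was -5.55 (SE 1.05), 46.8-fold higher in C. chinense, and it was the 1 of 71 families that passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0249). The call was lost without the stem library of C. chinense (log2 fold change -4.81, edgeR, Benjamini-Hochberg adjusted p = 0.198), or the stem (adjusted p = 0.161) or flower (adjusted p = 0.0567) library of C. frutescens. The value rests on few C. frutescens reads and moved to -6.45 without C. frutescens leaf, -6.41 without C. chinense leaf and -6.14 without C. chinense fruit, and to -4.68 with total reads and -4.93 with limma-voom. The copper-responsive miR398, which targets superoxide dismutases, had 3.62 (SE 1.28) and more reads per listed read in C. frutescens in 4 of 4 tissues, from 1.89-fold in leaf to 58.5-fold in fruit, and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.213). miR159 stood at 3.04 (SE 1.35), with 144-fold more in the fruit and 1.74-fold more in the leaf of C. frutescens, and did not pass either (edgeR, Benjamini-Hochberg adjusted p = 0.419).

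Of the other families with the largest one-way differences, which did not pass, miR8155 had a log2 fold change of 3.27, miR7767 of 2.21, miR168 of 2.12, miR319, a regulator of TCP genes, of 2.09, and miR4376 of 1.63. For miR5141 it was -3.03, from 2.30-fold more in C. chinense stem to 31.6-fold more in C. chinense leaf (104 reads against 1, counting interval 5.54 to 1259). miR8038 had no read in C. chinense and 14 and 21 in C. frutescens stem and fruit, and no read in flower or leaf of either species. Against the floor of 3 reads it was 5.82-fold and 4.58-fold higher per listed read in C. frutescens stem and fruit (lower counting limits 4.14 and 3.41). The fitted value of miR8038, 4.82, depends on the prior count, as does its place among the one-way families. The fitted values of all these families had the same sign under TMM, DESeq2 factors and total reads. The direction in each tissue was taken from shares of the listed reads, without TMM. In leaf the log2 ratios of miR168 (0.18) and miR319 (0.37) lie below the shift of 0.52 that TMM factors bring. With TMM factors these families therefore point toward C. chinense in leaf. The median log2 fold change of all families was 0.20 with TMM, 0.08 with DESeq2 factors and 0.90 with total reads.

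At an unadjusted p under 0.05 the edgeR test gave 8 families for the species contrast. DESeq2 called 12 families, 7 higher and 5 lower in C. frutescens, among them miR3711, miR894, miR398, miR159, miR319, miR166 and miR2599, and limma-voom called miR2599 alone. In edgeR further families passed when either fruit library or either leaf library was left out. For the species contrast each of these fits rests on the same pairs as the fit without that tissue's pair.

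**Figure D2:**
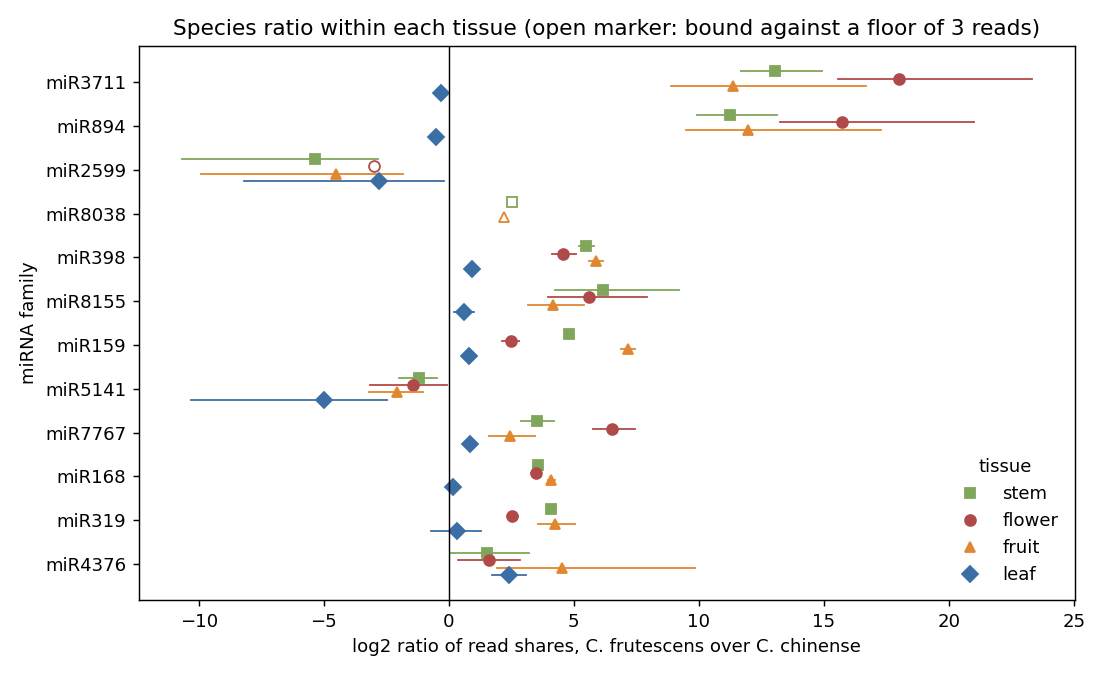
Log2 ratio of the read shares, C. frutescens over C. chinense (horizontal axis), of miR3711, miR894 and the 10 families with the largest differences that point one way in all 4 tissues, 1 marker per tissue with its 95% counting interval. Open markers are bounds against a floor of 3 reads, and miR3711 in leaf, 12915 reads against 52798, lies slightly below 0. miR8038, counted among the 10, had no reads in flower and leaf, where its direction came from the prior count and no marker is drawn.

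With all 8 libraries no list of families differed between the species by camera (all adjusted p at least 0.278), and no member passed when adjusted over the list alone. Of the 15 measured transcription factor and development families, 5 had positive and 10 negative log2 fold changes, with a median of -0.27. miR166 stood at -1.27, miR159 at 3.04, and miR396 at -0.13 with TMM but 0.59 with total reads. The 4 auxin families had a median of -0.35, with miR393, which targets auxin receptors, at 1.57 and miR160, which targets auxin response factors, at -0.27, a sign that turned to 0.61 with total reads. The 4 phase change families had a median of 0.88, with miR159 and miR319 positive and miR156, which targets SPL genes, at -1.01.

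Of the 5 nutrient families 4 were positive, with a median of 0.69, miR398 at 3.62 and miR408, a copper-responsive family, at 0.41. In the small RNA pathway list miR162 stood at -2.17 and miR168 at 2.12, with a list median of -0.20. With total reads the medians of the development, auxin and small RNA pathway lists turned to 0.59, 0.49 and 0.45. The 11 resistance gene and Solanaceae families had a median of 0.42, with miR482 at 0.16 and miR6027 at 1.13. The 4 MYB and phenylpropanoid families had a median of 0.86, with miR858 at 1.31. Of the 8 entries often traced to rRNA or tRNA fragments, 7 were positive, with a median of 1.22, miR894 at 10.09 and miR6300 at 1.22. Such fragments can be a sign of RNA breakdown, which was not checked here. This list had the lowest p for the species contrast and missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.278), but passed without C. frutescens fruit (camera adjusted p = 0.0454, 0.877 with an estimated correlation).

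Among tissues, the stem libraries held the most miR5723, with 12 and 75 reads against 3 in the other 6 libraries together, a log2 difference from the other tissues of 6.13 (SE 1.25). miR319 had 2.40 and miR390, which starts tasiRNA production for auxin response factors, 2.36. On the low side miR3711 stood at -4.23, miR6023 at -3.83 and miR894 at -3.67 in stem. The largest of these, miR5723, missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.0585). It passed without C. chinense fruit (adjusted p = 0.0440) or C. frutescens fruit (adjusted p = 0.0385), miR6023 turned to 1.01 without C. frutescens fruit, and without C. chinense leaf miR894 turned to 0.38 and miR3711 fell to -0.01.

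Among families with the same direction in both species, flower buds had the highest fitted values for miR3630 at 2.84 (SE 0.720), miR319 at 2.81 (SE 0.978) and miR6173 at 2.71 (SE 0.880). miR3630 had 104 and 74 reads in flower against 12 to 60 in the other libraries. miR2916, an entry often traced to rRNA or tRNA fragments, stood at -6.12 and the MYB-targeting miR858 at -3.82 in flower. The value of miR2916 here and in leaf rests on 10490 reads in C. chinense stem and 1816 in C. frutescens fruit, against 1 to 9 in each other library. miR5723 had no flower read in either species, and its fitted -4.02 depends on the prior count. None passed, the nearest being miR3630 (edgeR, Benjamini-Hochberg adjusted p = 0.194). Without C. chinense fruit 4 families passed in flower, miR3630 among them.

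In fruit, miR393 had 96 reads in C. chinense and 8696 in C. frutescens, against 10 to 42 in the other 6 libraries, a log2 difference of 5.27 (SE 1.21). In C. frutescens fruit 8661 of these reads, 99.6%, came from entries named for the 3p arm, not from the 5p arm known to target auxin receptors. miR6024, a Solanaceae family that targets resistance genes, had 4.59 (SE 1.30), and miR1446 had 3.45 (SE 0.912) with 20 and 114 reads. Low in fruit were miR3711 at -7.48, miR5139 at -5.41 and miR894 at -4.98, the last 2 being fragment entries. Without C. chinense leaf these were -3.64, -3.61 and -1.57, and without C. frutescens flower -4.69, -3.28 and -2.59. Without C. frutescens fruit miR393 was 2.34 and miR6024 0.58. miR393 missed the threshold over all families (edgeR, Benjamini-Hochberg adjusted p = 0.0962), as did miR6024 and miR1446 (both adjusted p = 0.124). Without C. chinense flower 3 families passed in fruit, without C. chinense fruit 6 and without C. frutescens fruit 1.

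**Figure D3:**
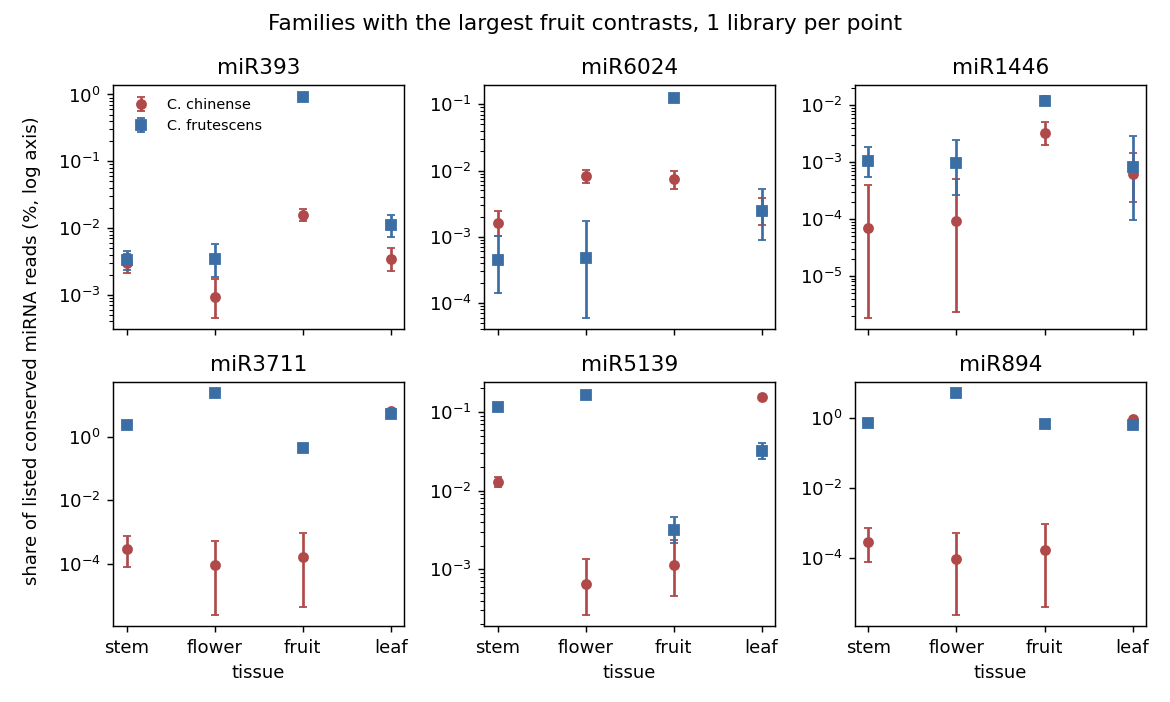
Share of the listed conserved reads (%, log axis) of 6 families in each tissue (horizontal axis), 1 point per library with its 95% Clopper-Pearson interval. These have the largest fruit contrasts per direction among families with the same direction in both species. miR393 lies highest in C. frutescens fruit, at 0.927%, and miR3711 and miR894 lie low in C. chinense stem, flower and fruit.

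In leaf, miR3711 stood at 11.04 (SE 3.60), miR7767 at 3.48 (SE 1.21) and miR6483 at 3.21 (SE 1.13), and miR2916 at -5.59, miR162 at -3.75 and miR319 at -3.62. The value of miR3711 rests on C. chinense leaf, without which it was -0.22. The lowest adjusted p in leaf was shared by miR3711, miR7767, miR6483, miR319 and others and missed the threshold (edgeR, Benjamini-Hochberg adjusted p = 0.191). Without C. chinense fruit 7 families passed in leaf, without C. frutescens fruit 9, without C. frutescens leaf 2 and without C. frutescens flower 1.

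The edgeR quasi-likelihood test called 0 families in each tissue contrast and in the joint test of all tissues, with 5, 6, 13, 12 and 12 families at an unadjusted p under 0.05 in stem, flower, fruit, leaf and all tissues together. DESeq2 called 5, 8, 13, 13 and 19 families, and limma-voom 0 in each. In the joint test 4 families passed without C. chinense flower, 17 without C. chinense fruit and 12 without C. frutescens fruit. The named families had the same sign in these contrasts under all 3 scalings, while the median of all families in the leaf contrast was -0.64 with TMM, -0.19 with DESeq2 factors and 0.48 with total reads. In flower these medians were 0.23, 0.05 and -0.64, in fruit 0.03, -0.05 and 0.39, and in stem -0.03, 0.08 and -0.43.

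Of the development families 12 of 15 lay lower in leaf than in the other tissues with TMM, with a median of -1.45 where all families had -0.64 (camera, Benjamini-Hochberg adjusted p = 0.0423). With total reads 10 of 15 lay lower, with a median of -0.47 (camera adjusted p = 0.119). By shares 9 of 15 lay lower in each species taken separately, not all the same families, with medians of -0.03 in C. chinense and -0.41 in C. frutescens. With an estimated correlation the adjusted p was 0.561, and no member passed by itself. The fry test, which asks whether a list differs from no change and not from the other families, gave 0.0734. The list also missed the threshold without C. chinense flower (camera adjusted p = 0.160), fruit (0.111) or leaf (0.137), or C. frutescens stem (0.0950), fruit (0.0601) or leaf (0.102).

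In the same contrast 7 of 8 fragment entries lay higher, with a median of 1.24 (camera adjusted p = 0.0447, 0.656 with an estimated correlation, 0.119 with total reads). Against no change fry gave 0.526. This rests on C. chinense leaf, without which 2 of 8 lay higher, with a median of -0.95 (camera adjusted p = 0.804). By shares within each species 7 of 8 were higher in C. chinense leaf and 4 of 8 in C. frutescens leaf, where miR894 stood at -1.06 against 11.98 in C. chinense. The list also missed the threshold without C. chinense flower (camera adjusted p = 0.365) or fruit (0.185), or C. frutescens stem (0.168) or fruit (0.0601). In fruit 7 of 8 fragment entries lay lower, with a median of -1.39 (camera, Benjamini-Hochberg adjusted p = 0.180), and the list passed without C. chinense flower (adjusted p = 0.0391) or C. frutescens leaf (adjusted p = 0.0172). By shares 7 of 8 lay lower in C. chinense fruit and 4 of 8 in C. frutescens fruit. All other lists had camera adjusted p of at least 0.0854 in every tissue, the lowest being the development and phase change lists in stem, with medians of 0.52 and 1.57. The phase change list passed in stem without C. chinense stem (camera adjusted p = 0.00725) or leaf (0.0419), and the fragment list in flower without C. frutescens flower (0.0369). With an estimated correlation no list passed in any contrast, with all libraries or with any 1 left out (lowest camera adjusted p 0.437).

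Adjusted over the list alone, members passed in fruit only among the 4 tissue contrasts. miR393 passed in the development list (edgeR, adjusted p = 0.0203) and in the auxin list (adjusted p = 0.00542), and miR6024 and miR1446 in the resistance gene and Solanaceae list (both adjusted p = 0.0289). In C. frutescens fruit 99.6% of the miR393 reads came from 3p entries, not from the arm known to target auxin receptors. The fruit values of miR393 and miR6024 fell when C. frutescens fruit was left out. The resistance list had a fruit median of 2.20 and the small RNA pathway list of 3.17, with camera adjusted p of 0.268 for both. By shares these medians were 0.28 and -0.53 in C. chinense and 2.39 and 5.50 in C. frutescens. The 5 nutrient families were all positive in fruit, with a median of 0.42 (camera adjusted p = 0.380), but 3 of 5 by shares in C. chinense alone. The MYB and phenylpropanoid list had a fruit median of 0.67 (camera adjusted p = 0.865), by shares 0.01 in C. chinense and 1.95 in C. frutescens.

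Within fruit, 39 of 57 families with at least 50 reads differed 4-fold or more between the species, 33 higher in C. frutescens and 6 in C. chinense. Among families read in both fruit libraries, miR894 had the highest ratio toward C. frutescens (1 read against 6112, 4000-fold, counting interval 718 to 158008). It was followed by miR3711 (1 against 4078, 2669-fold, 479 to 105434) and miR2916 (1 against 1816, 1188-fold, 213 to 46966). miR6023 had 0 reads in C. chinense fruit and 3514 in C. frutescens fruit, at least 767-fold against the floor (lower counting limit 623). This bound does not fix the rank of miR6023 among these ratios. Toward C. chinense the highest ratios were those of miR6025 with 242 reads against 10 (37.0-fold), miR1511 (10.7-fold) and miR5368 (6.09-fold). The median log2 ratio was 2.46, and 0.84 with TMM factors, when 33 families were apart, 23 higher in C. frutescens and 10 in C. chinense.

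In stem 17 of 49 families were apart, 14 higher in C. frutescens and 3 in C. chinense, a split of 11 and 7 with TMM factors. miR2916 had 10490 reads in C. chinense stem and 2 in C. frutescens stem (4208-fold, counting interval 1164 to 34748), miR2599 was 40.9-fold (7.02 to 1647) and miR394, which targets an F-box gene, 7.70-fold higher in C. chinense. miR3711 was 8396-fold, miR894 2464-fold and miR6025 147-fold (40.3 to 1222) higher in C. frutescens stem. In flower 19 of 40 were apart, 15 and 4. miR162 was 21.2-fold and miR6024 16.8-fold (88 reads against 2, 4.52 to 141) higher in C. chinense, and miR2599 8.03-fold against the floor of 3 reads (63 reads against 0, lower counting limit 6.34). miR3711 with 1 read against 102023 (266849-fold, counting interval 47893 to 1.05e+07), miR894 with 1 against 20562 (53782-fold, 9652 to 2.12e+06) and miR5139 with 7 against 673 (251-fold) were higher in C. frutescens flower.

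The leaf libraries were closest, with 4 of 42 families apart, 1 higher in C. frutescens and 3 in C. chinense (0 and 3 with TMM factors). miR5141 was 31.6-fold, miR6023 6.22-fold and miR5139 4.88-fold higher in C. chinense leaf, and miR4376, which targets a calcium ATPase, 5.29-fold, miR170 3.91-fold and miR6027 3.50-fold higher in C. frutescens leaf. These ratios compare 1 library with 1 and have no replicate check.

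By shares of the listed reads, 24 of the 71 families pointed one way in all 4 tissues, 21 toward C. frutescens and 3 toward C. chinense. If both directions were equally likely, 8.88 would do so by chance. The median log2 ratios were 1.09 in stem, 0.90 in flower, 1.71 in fruit and 0.26 in leaf. With such a shared lean toward C. frutescens the number by chance is higher. The 21 include miR8038 and miR5723, which had no read of either species in at least 1 tissue, where the sign came from the prior count. After the ratios of each tissue were centred on their median there were 17, of which 9 pointed toward C. frutescens and 8 toward C. chinense. Across these families, which are not independent replicates, libraries of the same tissue in both species had a mean Spearman correlation of 0.67, libraries of the same species 0.71 and libraries that share neither 0.63. The pairs across species had 0.64 in stem, 0.57 in flower, 0.53 in fruit and 0.92 in leaf. C. chinense leaf also had 0.85 with C. frutescens stem and 0.80 with C. frutescens flower, but 0.59, 0.58 and 0.61 with C. chinense stem, flower and fruit. Same-tissue pairs were not shown to be closer than other pairs across species (one-sided exact permutation p = 0.125 over 24 matchings, of which 0.0417 is the smallest possible). Without the fragment entries and miR3711, a choice made after seeing the data, p was 0.0417.

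**Figure D4:**
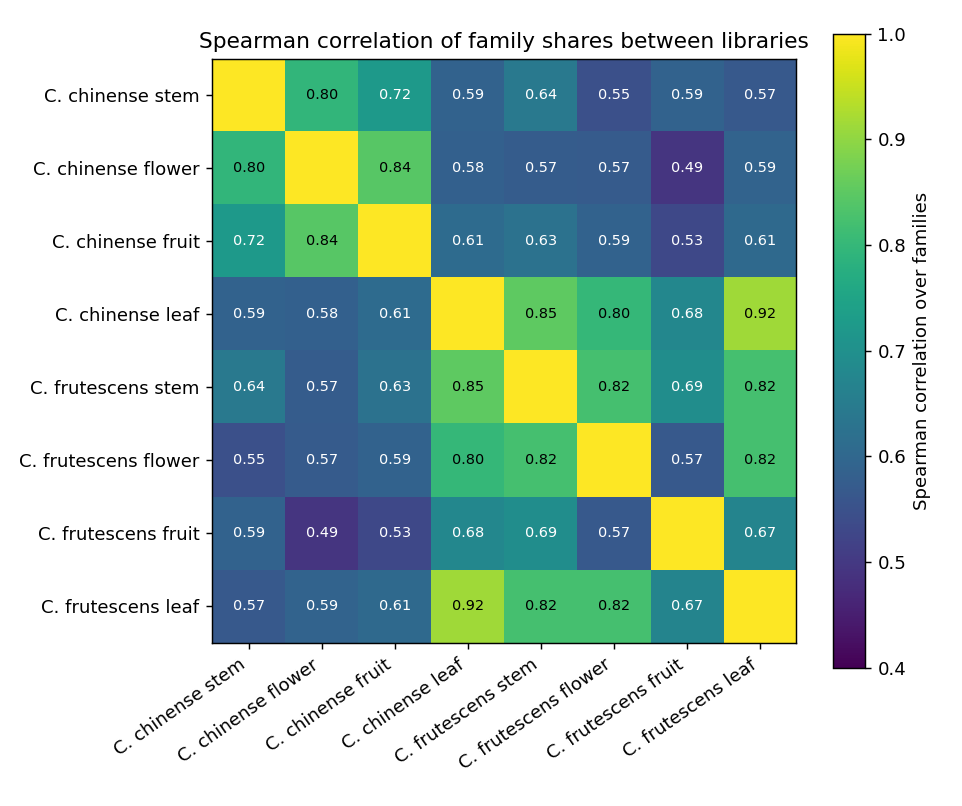
Spearman correlation over the 71 tested families (colour scale from 0.4 to 1) between each pair of the 8 libraries, with the value printed in each cell. The leaf libraries of both species have the highest correlation across species, 0.92, and the fruit libraries 0.53.

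The authors' predictions beyond the conserved entries comprised 3225 distinct sequences with 31422 reads, between 0.0995% and 1.60% of the listed reads of a library. C. frutescens fruit held 1227 sequences and 15250 reads, and C. chinense flower 812 sequences and 6628 reads. C. chinense stem, fruit and leaf held 431, 307 and 115 sequences, and C. frutescens stem, flower and leaf 262, 136 and 89. Of all sequences 3106 (96.3%) were listed in 1 library, 119 in at least 2 and 54 in both species, and 89.5% of the entries had fewer than 10 reads.

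The sequence with most reads was AUCUUGCCGAUUCCGUCCAUACCGCU, Cap-m0550-3p, with 4331 reads in C. frutescens fruit. A form 1 base shorter, AUCUUGCCGAUUCCGUCCAUACCGC, had 3010 reads in C. chinense flower and 1027 in C. frutescens flower. UUCGACAUUCCAGACAUGUUGGU (1001 reads), UUGGGUCGAAGUUUUGGAGGCCUU (725 reads) and GUCCUCUCUUUGUCUUGUUAUGU (631 reads) were listed in C. frutescens fruit alone. GAAAUCUUGCCGAUUCCCCCCCA was listed in 6 libraries, all but the flower libraries, with 136 reads in C. frutescens stem and 56 in C. chinense leaf, and UUUUUCACGAUGAUCGGGGUUAC in 4, with 94 reads in C. chinense stem. The other 6 sequences in 4 libraries had between 16 and 63 reads in all. The sequence with most reads, its shorter form and the sequence in 6 libraries share a run of bases at or near their start. They are thus not counted here as unrelated miRNAs. Whether these or other predicted sequences are variants of a conserved family was not tested.

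Predicted sequences were mostly 23 nt (36.3%) or 24 nt (34.3%) long, with 16.4% of 22 nt and 6.57% of 21 nt, and 29.9% began with U. Among sequences of up to 24 nt, 21 nt made up 6.69% of the predicted and 13.1% of the printed conserved ones (two-sided Fisher's exact test, p = 3.73e-19), and 24 nt 34.9% and 56.4% (p = 1.60e-73). A first base U was printed for 27.5% of all conserved sequences (Fisher's exact test, p = 0.0198). The printed conserved sequences vary between libraries, and these tests compare lists of sequences, not mature miRNAs. Sequences printed for the same entry in several libraries were counted separately and are not independent, so the p-values may be too small. In every library most conserved reads lay under longer printed sequences, which the length tests leave out.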

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

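The tests on shared predicted sequences and on the number of families in C. frutescens fruit were chosen after the results were seen, while the tests of depth and of fragment entries for the leaf pair were written down before theirs were, with the rule for judging fragment entries made stricter afterwards. In each species the 4 tissue libraries were compared for 1 library that stands far from the other 3. Of 28 such comparisons 12 found one. No number expected by chance is given. Most comparisons used families chosen for a high mean share in these libraries, which 1 extreme library can raise.

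C. chinense leaf stood apart from the stem, flower and fruit of its species in 6 of the families with most reads. Its miR166 share was 63.7% against 89.1% to 93.9% in the others, its miR6300 share 14.2% against 0.330% to 1.58%, and its miR3711 share 6.50% against at most 0.000283%. It also held 0.891% miR894, 0.402% miR159 and 0.611% miR168, each above the other C. chinense tissues. These shares lie nearer those of C. frutescens leaf, with 66.8% miR166, 8.87% miR6300, 5.24% miR3711, 0.630% miR894, 0.698% miR159 and 0.691% miR168.

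The leaf libraries of both species were the most alike of the 4 tissue pairs, with a Spearman correlation of 0.92 and a lead of 0.273 over the next pair. Depth does not account for it, since with every library thinned to the shallowest the lead was 0.268 (SD 0.0211 over 100 draws). The lead fell to 0.0952 without the fragment entries and miR3711, below the lowest of 1000 random removals of 9 families (0.110), but miR3711 had been added to that list because of its values, and the fixed list alone left 0.159, so the part played by these entries stays open. The 23 miR2599 and 104 miR5141 reads of C. chinense leaf, against 1 each in C. frutescens leaf, run against a library of C. frutescens RNA alone, though miR5141 did not pass in the species fit. A mixed library cannot be told apart from a true resemblance. The predicted sequences of C. chinense leaf recurred 22 times in the other C. chinense tissues and 17 times in those of C. frutescens (two-sided exact binomial p = 0.424). For C. frutescens leaf these numbers were 13 and 17 (exact binomial p = 0.588). A likeness of leaf miRNAs in both species, as the tissue labels would allow, remains untested with 1 library each.

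C. frutescens flower had the lowest miR6300 share of its species, 4.14%, and the highest miR894 share, 4.98%. C. frutescens fruit stood apart with 4.76% miR396, 2.78% miR162, 1227 predicted sequences and 15250 reads in them.

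C. frutescens fruit also listed 1008 conserved families, 1.90 times the next library. Its number of listed reads does not account for this. After thinning to equal reads it still listed 1.77 times as many as the library then next, C. frutescens leaf (SD 0.0537). Over C. frutescens stem, the next library as listed, the ratio was 1.90 as listed and 2.23 after thinning. With the reads other than miR166 thinned to 57695, the ratio over C. chinense flower was 1.08 (SD 0.0425), against 3.16 as listed and 2.85 with all reads thinned. Over C. chinense fruit it was 1.04 (SD 0.0392), against 3.20 and 2.30. The share of miR166 may account for what depth leaves of the lead over these 2, which were set apart by this outcome. Both ways of thinning also keep different numbers of reads. Over C. chinense stem and leaf the ratio was 1.36 (SD 0.0749) and 1.71, against 2.97 and 1.81 with all reads thinned. Over C. frutescens stem and leaf it was 1.63 and 1.58, against 2.23 and 1.77, and over C. frutescens flower 2.53, above the 2.07 with all reads thinned. A part of these leads is thus not accounted for by miR166. Other abundant families, such as miR482, miR3711 and miR6300, were not set aside, so their part in these leads was not tested. A richer set of miRNAs in this fruit stays untested, as the unlisted reads and the minimum for listing an entry are unknown.

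For 3 families the species ratio pointed in opposite directions in 2 tissues by at least 16-fold, and the difference was not tested, as each ratio rests on 1 library against 1. The log2 ratio (C. frutescens over C. chinense) of miR2916 was 10.21 in fruit and -12.04 in stem. It was 4.10 in fruit and -4.07 in flower for miR6024, and 7.20 in stem and -5.21 in fruit for miR6025. With TMM factors miR6024 had 2.48 in fruit, so that 2 families remained at 16-fold.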

How the results depend on the processing

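The removal of the leaf pair, the fruit pair or the fragment entries with miR3711, entry names as the unit, centred ratios, thinning without miR166, total reads and libraries left out for the list tests, and shared runs of 16 bases were chosen after the data were seen, as was the comparison of other groupings of the libraries. The 1 species call, miR2599, kept its direction and passed under both other scalings, DESeq2, limma-voom and 6 further alternatives of the fit, with adjusted p from 6.54e-08 to 0.0462. It no longer passed when either stem library or C. frutescens flower was left out, and was not tested at 50 reads in 4 libraries. Its log2 fold change was -6.44 without the leaf pair. Tissue is a block, and 8 groupings of the libraries have 1 library per tissue on each side, too few for a share under 0.05. The species gave 1 family past the threshold and the highest of the other 7 gave 0. At an unadjusted p under 0.05, 2 of these 8 groupings, the species included, gave 8 families, and the highest of all 32 that could be fitted gave 12.

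Counts of families moved as follows, and the cause was not tested unless stated. For the species contrast, DESeq2 gave 12, no filter 3, a filter of 50 reads in 4 libraries 3, the distinct sequence 0, the entry name 0, removal of the leaf pair 3 and of the fruit pair 3. The distinct sequence gives low counts by construction, because printed sequences differ between libraries. For all tissues together, DESeq2 gave 19, no filter 5, the 50-read filter 1 and removal of the fruit pair 2. In stem DESeq2 gave 5, no filter 1, removal of the fruit pair 5 and of the fragment entries 1. In flower DESeq2 gave 8 and removal of the fruit pair 2. In fruit total reads gave 1, DESeq2 13, no filter 1, the 50-read filter 5, no species block 1 and removal of the fragment entries 1. In leaf total reads gave 6, all higher in leaf, DESeq2 13, no filter 2, the 50-read filter 3 and removal of the fruit pair 3.

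With each library left out in turn, the counts ranged from 0 to 4 for species, 0 to 17 for all tissues, 0 to 1 in stem, 0 to 4 in flower, 0 to 6 in fruit and 0 to 9 in leaf. In the species contrast the library left alone in its tissue adds no comparison, because its own tissue term fits it. A fit without either library of a tissue thus rests on the same pairs as a fit without both. For miR2599 the log2 fold change was -6.41 without C. chinense leaf, -6.45 without C. frutescens leaf and -6.44 without the leaf pair. In the tissue contrasts the lone library is assumed to vary like the others. The log2 difference of miR6023 in stem ranged from -5.89 without C. frutescens stem to 1.01 without C. frutescens fruit, that of miR894 in stem from -3.95 without C. chinense flower to 0.38 without C. chinense leaf, and that of miR3711 in leaf turned to -0.22 without C. chinense leaf. Other families named for the largest differences kept their direction, while list members such as miR396 and miR160 turned in the species contrast with total reads. Of the values of the families named for the largest differences in the species fit 169 stayed on the same side of the threshold, 9 newly passed and 3 no longer passed, and in the tissue fits 359 stayed and 51 newly passed.

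Families apart within a tissue numbered 32 in stem, 31 in flower and 8 in leaf with a minimum of 10 reads, and 9, 12 and 1 with a minimum 10 times that of the report. At 2-fold they numbered 30 in stem, 29 in flower and 15 in leaf, and at 8-fold 1 in leaf. These shifts in number follow from the thresholds. Of the named ratios 7 of 24 moved beyond their counting interval with TMM factors and none changed direction. The lists past the threshold fell from 2 to 0 with an estimated correlation and to 0 with fry, 0 with total reads, and 0 to 3 with each library left out, all of them 0 with an estimated correlation. The permutation p of the same-tissue correlation was 0.0417 without the fragment entries and miR3711, 0.208 with Pearson's correlation and 0.292 over families listed in all libraries. C. frutescens fruit listed 3.16 times the median families of the other libraries, 1.74 times with at least 10 reads and 1.58 times when reads other than miR166 were thinned. Predicted sequences in at least 2 libraries numbered 119 of 3225 (3.69%), 24 of 323 with at least 10 reads, a larger share, and 222 of 2928 groups by shared runs of 16 bases. Weighted by reads, 59.3% of the predicted sequences were of 23 or 24 nt and 27.4% began with U. Counting each distinct conserved sequence once changed no share of miR166, as no library lists a conserved sequence under more than 1 name. The pseudocount alternatives were not run, because the values are counts.

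Depth limits the rare families most. In C. frutescens leaf, the shallowest library, a family without reads can still have a share of up to 0.00122%, and at the observed spread between libraries the simulated fit recovered few changes of 4-fold.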

Other observations

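All tests in this part were chosen after the data were seen. In C. frutescens fruit the arm of the miRNA duplex that is usually degraded held a larger part of the reads than elsewhere, for 5 of the 10 families examined. Entries named for the 3p arm held 32.5% of the miR396 reads there and at most 8.80% in any other library, and entries named for the 5p arm 38.4% of the miR162 reads, against at most 12.0%. For miR482 the 5p arm held 9.29% against at most 0.379%, and for miR166 1.76% against at most 0.235%. The 3p arm of miR393 held 99.6% of 8696 reads in this library, but also most of the 10 to 96 reads in each of the others, from 64.3% in C. chinense leaf to 9 of 10 reads in C. chinense flower. The remaining 5 families, miR159, miR168, miR172, miR319 and miR390, had their highest such share in another library, among them 50.2% for miR159 in C. chinense stem and 29.8% for miR168 in C. chinense fruit. No explanation of these shares was tested.

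Of the 3350 conserved entries with 1 read, 48.6% had a printed sequence of 24 nt and 11.3% one of 21 nt. One hypothesis is that some of these are reads of 24-nt siRNAs, which often begin with A, listed under conserved names. A first base A was more frequent at 24 nt than at 21 nt in 8 of 8 libraries (1042 of 1628 entries against 110 of 377 over all, two-sided exact sign test p = 0.00781), which is consistent with the hypothesis. That the reference names matched by these reads are themselves of 24 nt with a first base A was not tested and stays open, and families known from 1 read each may not be miRNAs of these plants.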
